A study of Mus musculus with 12 samples.

How the data were processed

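Gene expression was measured by RNA sequencing in 12 libraries of Lin- Sca-1+ Kit+ (LSK) cells, the fraction that holds blood stem cells and early progenitors. The cells came from bone marrow or spleen of female NZBW/F1 mice, a hybrid strain prone to lupus. Per the labels' protocols, mice received 1 mg of β-glucan, a polysaccharide of fungal cell walls, in 200 µL of PBS, or PBS alone, by intraperitoneal injection every 15 days from 3 to 6 months of age. The labels' protocols name TruSeq v2 mRNA libraries read single-end over 75 bases. The 4 groups of 3 libraries were taken from the source labels, replicate numbers follow the order of deposit, and no label says which marrow and spleen came from one mouse, so no pairing was used.

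Per the submitters' processing notes, the tools were FastQC, STAR 2.6, HTSeq and edgeR, and the genome build was mm10. Their roles, the gene annotation and the strand setting of the counting are not given in the sources used here. The authors deposited one table of normalized signal per gene and library, named CPM, with 15008 genes whose highest value was 0.953 or more. Column totals ran from 788559 to 1537461, so the deposited signal was not plain CPM. All deposited values (100% in each library) were whole multiples of a library-specific step within 0.01 read, which gave back whole reads per gene. The trimmed-mean scaling of edgeR, applied to those reads, returned the deposited library sizes (ratio 1 in each library). The values are therefore called scaled CPM below. The test had been fixed for CPM; since the unit is a scaled signal, limma on log values stayed the main test and the count models were run on the recovered reads as alternatives.

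The recovered depth was 15547016 to 20551557 reads per library, and 1 read was worth 0.0397 to 0.085 scaled CPM. For shares of reads in a single library, the 95% Wilson interval was at most 0.0487 percentage points wide for immunoglobulin genes and 0.446 for V segments. These intervals cover counting error only, because reads without molecular identifiers are not independent molecules. Symbols and coordinates came from GENCODE M21 on GRCm38: 14777 identifiers matched, 11 of them with the version number, and 231 did not and kept their identifier. Immunoglobulin V segments, Mcpt1 and its neighbours of the chymase family, Iigp1, Tgtp1, H2-Ea-ps and Hba-a1 share sequence with close copies, so their values are uncertain. Reads of antisense or overlapping genes could not be told apart.

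Values were tested as log2(value + 1) for 14100 genes with at least 1 scaled CPM in at least 3 libraries. Fold changes are on that scale, which understates changes of low genes. limma 3.58.1 in R 4.3.3 fitted one mean per group over all 12 libraries (8 residual degrees of freedom, trend and robust variance). Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were β-glucan against PBS in marrow, in spleen and averaged over both, the difference of the effect between tissues, and spleen against marrow in PBS mice and in β-glucan mice. The 26 disjoint gene lists (571 genes) were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists. Camera with a correlation estimated per list and fry, which asks whether a list moved on balance one way or in either direction, were alternatives. Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined.

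The rule named, per contrast, up to 10 called genes per direction with the largest fold change (5 for the difference between tissues). Their groups had to be free of overlap, except for the difference between tissues, with a mean of at least 5 in the higher group, and predicted genes were left out. It added up to 4 called members of each list, and 13 genes of stem and progenitor biology in the treatment and tissue contrasts. Where no gene was called, up to 3 per direction with the smallest p were named. Single values such as the immunoglobulin share were compared by exact permutation, where 3 libraries against 3 give no p under 0.1. Correlations over 12 libraries used 100000 permutations.

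The alternatives were pseudocounts of 0.25 and 4, no filter or a minimum of 5, median-of-ratios and quantile scaling, array weights, no robust variance, only the groups compared, each library left out in turn, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 tests on recovered reads. Added after seeing the data were a plasma score (mean log2 value of 11 plasma cell genes that are not immunoglobulin genes) as covariate, the farthest library of each group left out, and scaling with the immunoglobulin genes removed. In data simulated from the library means, log2 changes of 1 were recovered in 59% of genes for β-glucan in marrow, 61% in spleen, 55% for tissue in PBS mice and 59% in β-glucan mice. For log2 changes of 2 the shares were 97%, 94%, 90% and 99%, with 11, 13, 12 and 14 false calls among 14165, 13692, 13936 and 14069 genes. The simulation drew each gene independently, while genes varied together in the real libraries (estimated correlation 0.93 in the ribosomal protein list). Its shares and false calls may therefore not hold for the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.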

Results

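RNA was sequenced from LSK cells of bone marrow and spleen of lupus-prone NZBW/F1 mice given β-glucan or PBS, with 3 libraries in each of the 4 groups. The depth was 15547016 to 20551557 reads per library. Values are scaled CPM, given as mean ± SD with n = 3, and fold changes are log2 values from limma with their SE. The labels do not say that the libraries of a group came from separate mice, so p-values measure the spread between these samples. None of the 66 pairs of libraries agreed within sampling noise (lowest chi-square per degree of freedom 16.3). The tissue names follow the labels.

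Kit, the receptor used for the sort, had 322 ± 45.4 in marrow PBS, 298 ± 25.3 in marrow β-glucan, 285 ± 19.7 in spleen PBS and 336 ± 19.9 in spleen β-glucan. Ly6a, which encodes Sca-1, had 342 ± 101, 434 ± 111, 754 ± 422 and 541 ± 185 in the same order, and neither gene was called in any treatment or tissue contrast. Immunoglobulin genes, the products of B lineage cells, made up 21.0% ± 8.73 of reads in marrow PBS and 35.5% ± 7.65 in marrow β-glucan. In spleen they made up 48.0% ± 8.03 with PBS and 32.5% ± 9.38 with β-glucan (SD, n = 3). Exact permutation tests gave p = 0.2 for β-glucan in marrow, 0.2 in spleen, 0.1 for tissue in PBS mice and 0.9 in β-glucan mice, where 0.1 is the smallest possible. Ighm, the heavy chain of IgM, was the most abundant gene in each of the 12 libraries, with 6.39% to 28.9% of reads.

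**Figure D1:**
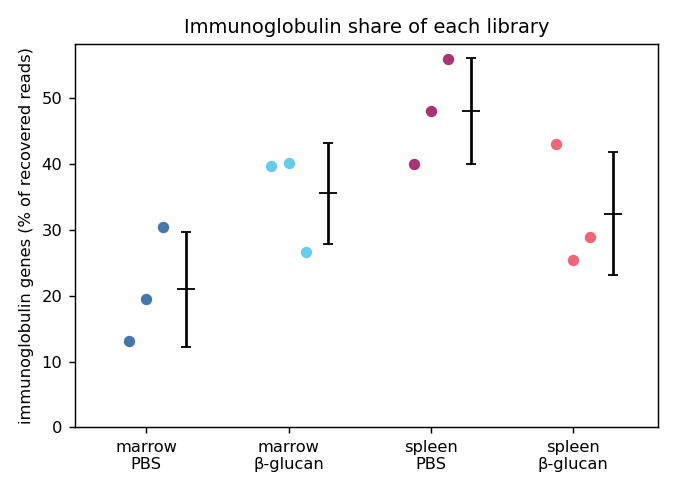
Percent of recovered reads from immunoglobulin genes (y axis) in each library (points) by group (x axis), with mean and SD bars of 3 libraries. Group means run from 21.0% in marrow PBS to 48.0% in spleen PBS.

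Over the 12 libraries, mean log2 values of 8 gene groups were set against the immunoglobulin share, with permutation p-values adjusted over those 8. The permutations shuffled all 12 libraries without regard to group, although groups differed in that share, so these p-values may be too small. The non-immunoglobulin plasma cell genes had r = 0.990 and rho = 0.979 (p = 1e-05 for each, the smallest the permutations can give, adjusted 8e-05). Without the 2 libraries farthest from the median share r was 0.987, and within marrow and spleen it was 0.990 and 0.991 (6 libraries each). The G2/M list of cell division genes had r = -0.91 (permutation p = 4e-05, adjusted 0.00016) and rho = -0.94 (p = 3e-05, adjusted 0.00012). Without the 2 farthest libraries r was -0.81, and it was -0.90 in marrow and -0.99 in spleen. The interferon-stimulated list had r = -0.85 (permutation p = 0.00063, adjusted 0.00168) and rho = -0.82 (p = 0.00179, adjusted 0.00477). Its r was -0.74 without the 2 farthest, -0.65 in marrow and -0.94 in spleen. The other 5 groups, B cell, HSC, granulocyte-monocyte progenitor, dendritic cell and T and NK cell, had adjusted p of 0.187 or more.

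The first comparison asked how β-glucan changed marrow LSK cells. Slpi, a secreted inhibitor of neutrophil elastase, rose from 21.7 ± 6.59 to 118 ± 26.9 (log2 fold change 2.40, SE 0.24, limma adjusted p = 0.00418). Mcpt1, a mast cell protease, fell from 19.2 ± 9.58 to 1.64 ± 0.743 (log2 fold change -2.87, SE 0.30, adjusted p = 0.00418). Slpi lies on chromosome 2 at 164354070 to 164389095 and Mcpt1 on chromosome 14 at 56017971 to 56020384 (GENCODE M21, GRCm38). These were the 2 genes called of 14100, while 1145 had an unadjusted p under 0.05 against 705 by chance. None of the 13 stem and progenitor genes was called. Mpo, the granule enzyme of granulocyte-monocyte progenitors, had 234 ± 92.4 with PBS and 915 ± 907 with β-glucan (adjusted p = 0.623). Slamf1, a stem cell surface marker, had 6.48 ± 2.75 and 10.6 ± 1.41 (adjusted p = 0.516). Clec7a, the β-glucan receptor Dectin-1, had 2.58 ± 0.592 and 2.23 ± 0.803 (adjusted p = 0.945). Neither gene was called when only the 6 marrow libraries were fitted (adjusted p = 0.152 for Slpi and 0.264 for Mcpt1). The count was 9 with a pseudocount of 4, 20 with array weights (a fit that did not converge), 116 with DESeq2, 4 with the plasma score, 17 without the farthest libraries and 4 without marrow PBS replicate 1.

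Camera with the preset correlation called 8 of the 26 lists in marrow, and no list member passed over all genes. The interferon-stimulated list was shifted lower (28 of 31 members negative, median -0.43), with adjusted p = 0.184 with an estimated correlation and a fry adjusted p of 0.0491. Adjusted over the list alone, 9 of its members fell, and Gbp2, a GTPase of antimicrobial defence, had 86.6 ± 8.92 with PBS and 50.9 ± 4.24 with β-glucan. MHC class II presentation was shifted lower (13 of 13 members negative, median -0.78), with adjusted p = 0.188 with an estimated correlation, and 9 members fell adjusted over the list alone. Its member H2-DMb1, which loads peptides onto class II, had 85.2 ± 36.9 with PBS and 36.2 ± 2.31 with β-glucan. Beside it, the dendritic cell markers Xcr1 (138 ± 38.1 and 58.2 ± 19.0) and Clec9a (38.7 ± 14.5 and 19.7 ± 3.86) had lower means with β-glucan. Neither was called (limma adjusted p = 0.204 and 0.3). The dendritic cell list as a whole was not called and was split, with 8 members positive and 9 negative. Adjusted over the list alone, 2 of its members rose and 3 fell. Plasma cell genes were shifted higher (median 0.90; adjusted p = 0.855 with an estimated correlation), with 3 higher adjusted over the list alone, beside an immunoglobulin share of 35.5% against 21.0%. Granulocyte-monocyte progenitor (median 0.37) and mature neutrophil (0.27) lists were shifted higher, with adjusted p = 0.921 for each with an estimated correlation and 0 and 2 members higher adjusted over the list alone. G2/M (-0.34), ribosomal protein (-0.22) and oxidative phosphorylation (-0.13) lists were shifted lower, with adjusted p = 0.921 for each with an estimated correlation and 0 members adjusted over the list alone. With the plasma score the G2/M, ribosomal protein and oxidative phosphorylation lists turned direction (adjusted p = 0.000216, 0.0914 and 0.0241). Without marrow PBS replicate 1 the oxidative phosphorylation and ribosomal lists turned (0.0894 and 0.624) and 5 lists were called, and without the farthest libraries oxidative phosphorylation turned (0.972).

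The second comparison asked how β-glucan changed spleen LSK cells. Slpi fell from 177 ± 18.7 to 50.6 ± 13.1 (log2 fold change -1.81, SE 0.24, limma adjusted p = 0.0424). Manf, a protein of the endoplasmic reticulum stress response, fell from 329 ± 6.50 to 181 ± 13.6 (-0.87, SE 0.12, adjusted p = 0.0463). The immunoglobulin segments Ighv1-63 (-3.28, SE 0.42, adjusted p = 0.0424) and Igkv14-100 (-3.32, SE 0.46, adjusted p = 0.0463) also fell. No gene was called higher, and 1313 genes had an unadjusted p under 0.05 against 705 by chance; edgeR called 0 and DESeq2 33 higher and 81 lower. None of the 13 stem and progenitor genes was called: Gata1, the erythroid regulator, had 12.7 ± 3.84 with PBS and 25.7 ± 8.75 with β-glucan (adjusted p = 0.448). The count of 4 became 2 with no filter, 0 with quantile scaling, only the spleen groups, edgeR or immunoglobulin genes removed (2 of the 4 among them), 3621 with array weights, 114 with DESeq2 and 39 without the farthest libraries, and with the plasma score 0 of the 4 were called while 3 others were higher (Iigp1 1.47, Ighg2c 3.07 and Ighv14-3 1.43). The 4 kept their sign with that score: Slpi -1.50 (SE 0.25, adjusted p = 0.0751), Manf -0.83 (SE 0.14, 0.0751), Igkv14-100 -2.84 (SE 0.61, 0.175) and Ighv1-63 -2.68 (SE 0.48, 0.114). It was 0 without marrow PBS 2, marrow β-glucan 2, spleen PBS 1, 2 or 3, or spleen β-glucan 2 or 3, 2 without marrow β-glucan 1 and 1 without marrow β-glucan 3.

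Camera with the preset correlation called 13 lists in spleen, with 0 members past the threshold over all genes. The interferon-stimulated list was shifted higher (27 of 31 members positive, median 0.44), with adjusted p = 0.299 with an estimated correlation and a fry adjusted p of 0.0438. Adjusted over the list alone, 14 members rose, and Ifih1, a sensor of viral RNA, had 20.1 ± 1.34 with PBS and 33.3 ± 2.88 with β-glucan. Plasma cell genes were shifted lower (median -0.92), with adjusted p = 0.647 with an estimated correlation, and 5 were lower and 1 higher adjusted over the list alone. Creld2, an endoplasmic reticulum chaperone of that list, had 652 ± 103 with PBS and 277 ± 76.8 with β-glucan, beside an immunoglobulin share of 48.0% against 32.5%. Erythroid genes (21 of 21 positive, median 0.68) and G2/M genes (24 of 24, 0.56) were shifted higher, with adjusted p = 0.647 for each with an estimated correlation and 0 members adjusted over the list alone. S phase (0.41) and HSC (0.30) lists were shifted higher, with adjusted p = 0.674 for each with an estimated correlation. Megakaryocyte (0.35), stroma (0.36) and class II (0.15) lists were shifted higher, with adjusted p = 0.647, 0.711 and 0.711 with an estimated correlation. Immediate early (-0.44), mature neutrophil (-0.28), cholesterol synthesis (-0.14) and oxidative phosphorylation (-0.08) lists were shifted lower, with adjusted p = 0.647, 0.674, 0.647 and 0.876 with an estimated correlation. Adjusted over the list alone, 1 stroma, 1 class II and 2 immediate early genes passed. With the plasma score the erythroid, S phase and G2/M lists turned direction (adjusted p = 0.822, 0.011 and 0.432). Without spleen PBS replicate 1 or spleen β-glucan replicate 1, 8 lists were called.

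The third comparison asked whether the β-glucan effect differed between the tissues. The difference (spleen effect minus marrow effect) was called for 54 genes, 23 positive and 31 negative, and 53 of them had effects of opposite sign. Choosing genes by a large difference favours opposite signs, so that count is no separate evidence that the effects were opposed. Slpi differed most by p (-4.22, SE 0.34, limma adjusted p = 0.000392). Iigp1, an interferon-inducible GTPase, had 72.8 ± 24.1 and 31.3 ± 2.10 in marrow and 9.34 ± 0.0975 and 22.2 ± 2.94 in spleen, with PBS and β-glucan (2.30, SE 0.27, adjusted p = 0.0122). Ccn3 (2.21), H2-DMb1 (2.05) and the fatty acid receptor Cd36 (1.55) also differed upward. Mcpt1 (2.87) had about 0.05 in both spleen groups, so its difference came from marrow. All 8 immunoglobulin genes among the calls were negative, among them Ighv12-3 (-6.40), Ighv1-63 (-4.95), Igkv14-100 (-4.51) and Igkv1-99 (-4.13), beside immunoglobulin shares that went from 21.0% to 35.5% in marrow and from 48.0% to 32.5% in spleen. The plasma cell gene Creld2 (-2.07) and the stress gene Gadd45b (-1.67) were negative too. Across genes, effects in the tissues had r = -0.51 and rho = -0.38, and 61.2% had opposite signs; genes are not independent replicates, and the contrasts share no library. At an unadjusted p under 0.01 in each tissue, 0 genes moved the same way and 68 opposite ways against 4.37 by chance.

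**Figure D2:**
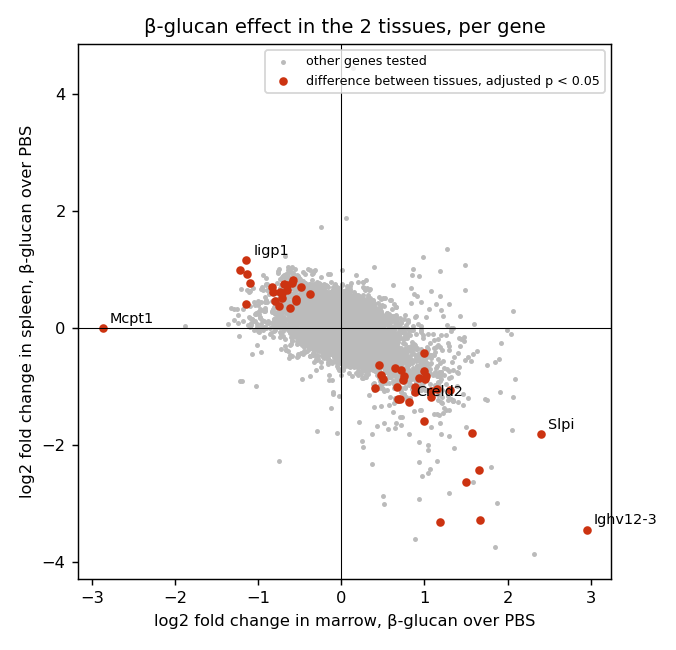
Log2 fold change of β-glucan over PBS in marrow (x axis) and spleen (y axis) for the 14100 genes tested, with the 54 called for a difference in red. Slpi lies at 2.40 and -1.81.

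Camera called 9 lists for this difference, none with an estimated correlation. The interferon-stimulated list (median 1.13; adjusted p = 0.123 with an estimated correlation; fry adjusted p = 0.00429) had 5 members called, 21 adjusted over the list alone, among them Cmpk2 (1.30), Ifih1 (1.19), Gbp2 (1.13) and Ifit1 (1.37). The class II list (median 1.00; adjusted p = 0.620 with an estimated correlation) had 1 member called, 8 adjusted over the list alone. The dendritic cell marker Xcr1 had a difference of 1.57 (SE 0.39, adjusted p = 0.0984) and was not called. The dendritic cell list was not called either, with 3 members higher and 3 lower adjusted over the list alone. The plasma cell list (-1.83; adjusted p = 0.732 with an estimated correlation) had 1 called, 15 lower and 1 higher adjusted over the list alone. Medians were 1.32 for erythroid, 0.86 for G2/M, 0.52 for S phase, -0.72 for immediate early, -0.51 for mature neutrophil and -0.18 for cholesterol synthesis genes. Their adjusted p = 0.870, 0.802, 0.870, 0.823, 0.802 and 0.870 with an estimated correlation. Adjusted over the list alone, 5 G2/M genes differed upward, and 3 immediate early and 2 neutrophil genes downward. The count of 54 genes became 1602 with array weights, 537 with DESeq2, 459 without the farthest libraries and 34 with the plasma score, of which 8 were among the 54. Without a call there, Mcpt1 had 2.37 (SE 0.60), H2-DMb1 1.40 (SE 0.40), Igkv14-100 -3.52 (SE 1.02), Ighv1-63 -3.72 (SE 0.80) and Creld2 -1.08 (SE 0.25). Creld2 is among the 11 genes that make up the plasma score, so its smaller difference with that score is partly built in. Calls were kept by Slpi (-3.58, limma adjusted p = 0.0066) and Iigp1 (2.94, 0.00201). Ifih1 (1.45), Gbp2 (1.34) and Manf (-1.29) kept theirs too (limma adjusted p = 0.046 for each). With that score the erythroid, S phase and G2/M lists turned direction (adjusted p = 0.0705, 3.29e-07 and 0.018). Leaving out marrow PBS replicates 1, 2 and 3 gave 14, 1 and 121 genes, marrow β-glucan replicates 1, 3 and 11, spleen PBS replicates 10, 1 and 9, and spleen β-glucan replicates 213, 2 and 3.

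Averaged over both tissues, β-glucan changed no gene by limma (smallest adjusted p = 0.296, for Mcpt1), with 382 genes at an unadjusted p under 0.05 against 705 by chance; edgeR called 0, DESeq2 1. Inf2, an actin regulator, was the gene named by rule and was not called (0.34, SE 0.11). Camera called 11 lists, with 0 members past the threshold over all genes and 1 erythroid gene adjusted over the list alone. HSC (0.22), T and NK cell (0.21), megakaryocyte (0.20), erythroid (0.17), S phase (0.13) and G2/M (0.11) lists were shifted higher. Class II (-0.22), mitochondrially encoded (-0.14), immediate early (-0.13), ribosomal protein (-0.13) and oxidative phosphorylation (-0.12) lists were shifted lower. G2/M had adjusted p = 0.701 with an estimated correlation and the other 10 had adjusted p = 0.674 with an estimated correlation. The count of genes was 3 with array weights and 1 without marrow PBS replicate 3. G2/M turned direction without marrow PBS 3 (adjusted p = 0.977), immediate early without spleen PBS 2 (0.863), T and NK cell without spleen β-glucan 2 (0.634) and HSC without the farthest libraries (0.506).

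The fourth comparison set spleen against marrow LSK cells in PBS mice. In libraries labelled spleen, 1260 genes were higher and 1413 lower, 579 and 767 of them by over 1 log2 unit. Genes of type 1 conventional dendritic cells were far lower: Xcr1, their chemokine receptor, had 1.89 ± 0.386 against 138 ± 38.1 in marrow (-5.56, SE 0.27, limma adjusted p = 9.68e-08), and Clec9a 0.925 ± 0.451 against 38.7 ± 14.5 (-4.33). H2-Aa, a class II chain, had 37.6 ± 8.75 against 1674 ± 716 (-5.38, SE 0.26, adjusted p = 8.38e-08), and Ciita, the class II regulator, 4.09 ± 1.20 against 203 ± 27.5 (-5.35). Dnase1l3 (-6.05), Plbd1 (-5.62), Cxcl9 (-5.58), Zfp366 (-5.47), Adam23 (-5.41), H2-Ea-ps (-5.38) and Cd8a (-5.33) completed the 10 largest falls. Mpo had 2650 ± 1795 against 234 ± 92.4 (3.27, SE 0.74, adjusted p = 0.0102), and Cebpa, a granulocyte regulator, 46.0 ± 20 against 10.3 ± 1.97 (1.98, adjusted p = 0.00301). Procr (-1.35), Irf7 (-1.18) and Gata1 (-1.95) were lower. The plasma score moved Mpo to 6.23 (SE 0.79) and Cebpa to 3.50 (SE 0.36), so the size of these rises depends on that choice. The 10 largest rises were immunoglobulin segments, such as Igkv1-88 (5.59) and Ighv5-16 (5.26), beside an immunoglobulin share of 48.0% against 21.0%.

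**Figure D3:**
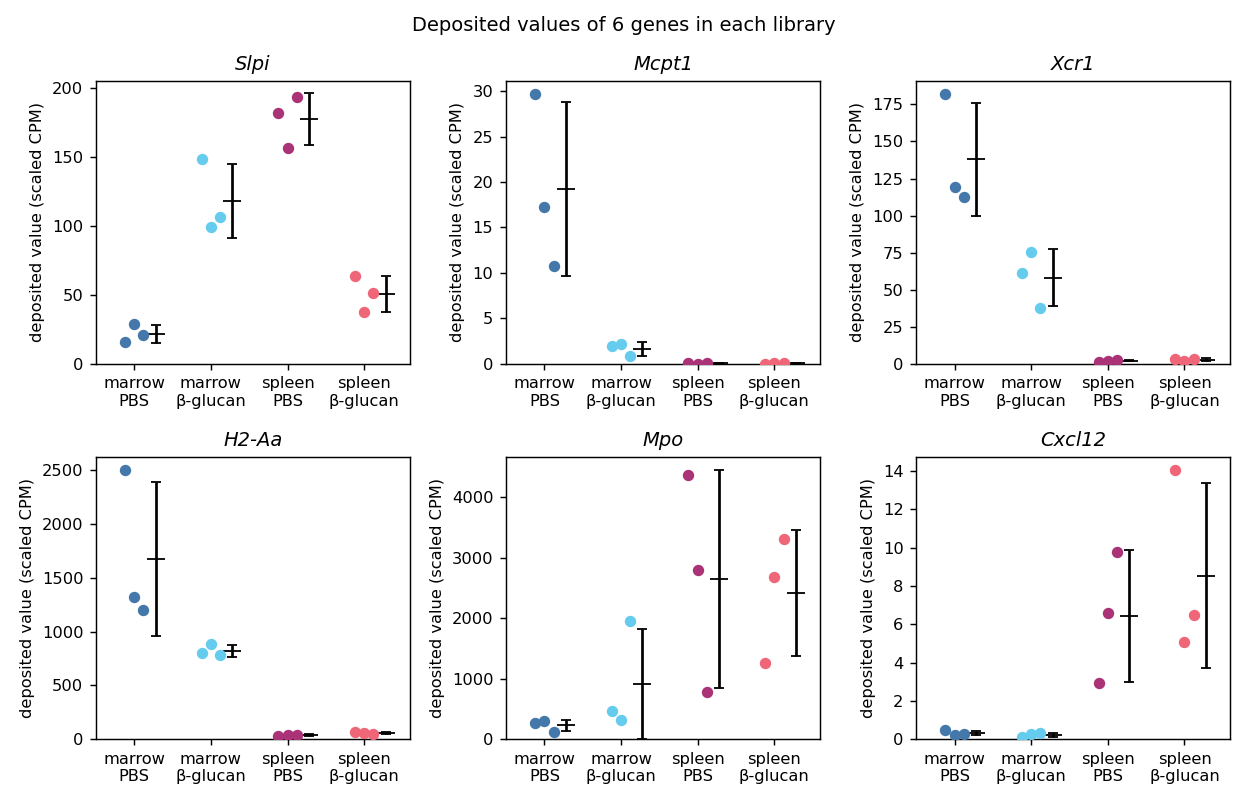
Scaled CPM (y axis) of 6 genes in each library (points) by group (x axis), with mean and SD bars of 3 libraries. Xcr1 had 138 in marrow PBS and 1.89 in spleen PBS, and Slpi 21.7 and 177.

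Camera called 15 lists between tissues in PBS mice. MHC class II (12 of 13 lower, median -3.97), interferon-stimulated (24 of 31 lower, -1.17) and inflammatory (14 of 23 lower, -1.07) lists had adjusted p = 0.0565 for each with an estimated correlation. Monocyte-macrophage (14 lower and 1 higher of 20, -1.40) and dendritic cell (9 lower and 3 higher of 17, -1.34) lists had adjusted p = 0.0565 for each with an estimated correlation. Gbp2 (-1.89) fell in the interferon list, and Cd83 (-3.70) and Cd40 (-2.40) in the inflammatory list. Macrophage genes included Vcam1 (-2.16) and Treml4 (-3.59). Granulocyte-monocyte progenitor genes (11 higher, 2 lower and 10 not past of 23, median 1.16) included Ly6c2 (2.30) and Irf8 (-1.84), with adjusted p = 0.624 with an estimated correlation. Mature neutrophil genes (12 of 15 higher, 1.30) included Lcn2 (2.47) and S100a8 (2.57), with adjusted p = 0.142 with an estimated correlation. Plasma cell genes (13 higher and 1 lower of 19, 1.59) included Creld2 (1.80) and Derl3 (2.08), with adjusted p = 0.550 with an estimated correlation. T and NK cell (8 of 22 lower), erythroid (12 of 21), HSC (6 of 25) and megakaryocyte (5 lower, 1 higher of 16) lists had adjusted p = 0.492, 0.558, 0.701 and 0.626 with an estimated correlation. Mast cell (6 lower, 2 higher of 16), S phase (0 of 25) and G2/M (2 of 24 lower) lists had adjusted p = 0.142, 0.730 and 0.624 with an estimated correlation. Adjusted over the list alone, 12 class II, 25 interferon, 16 inflammatory, 14 macrophage, 9 dendritic, 12 T and NK and 14 erythroid genes were lower, and 12 progenitor, 13 neutrophil and 14 plasma cell genes higher. In the opposite direction, 4 dendritic genes and 1 macrophage gene were higher, and 3 progenitor genes, 2 neutrophil genes and 1 plasma cell gene lower. The stromal chemokine Cxcl12 had 6.43 ± 3.43 in spleen and 0.339 ± 0.125 in marrow (2.36). Higher genes numbered 537 with the plasma score, 761 with only the PBS groups, and 664, 787 and 753 without marrow PBS 2, spleen PBS 2 and spleen PBS 3; the score kept 28.7% of all calls and ended those of Cxcl12 (1.44) and Irf7 (-1.04). It turned the erythroid, S phase and G2/M lists (adjusted p = 0.567, 1.19e-08 and 9.35e-05) and Cenpe (0.05), and S phase turned without the farthest libraries (0.774).

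**Figure D4:**
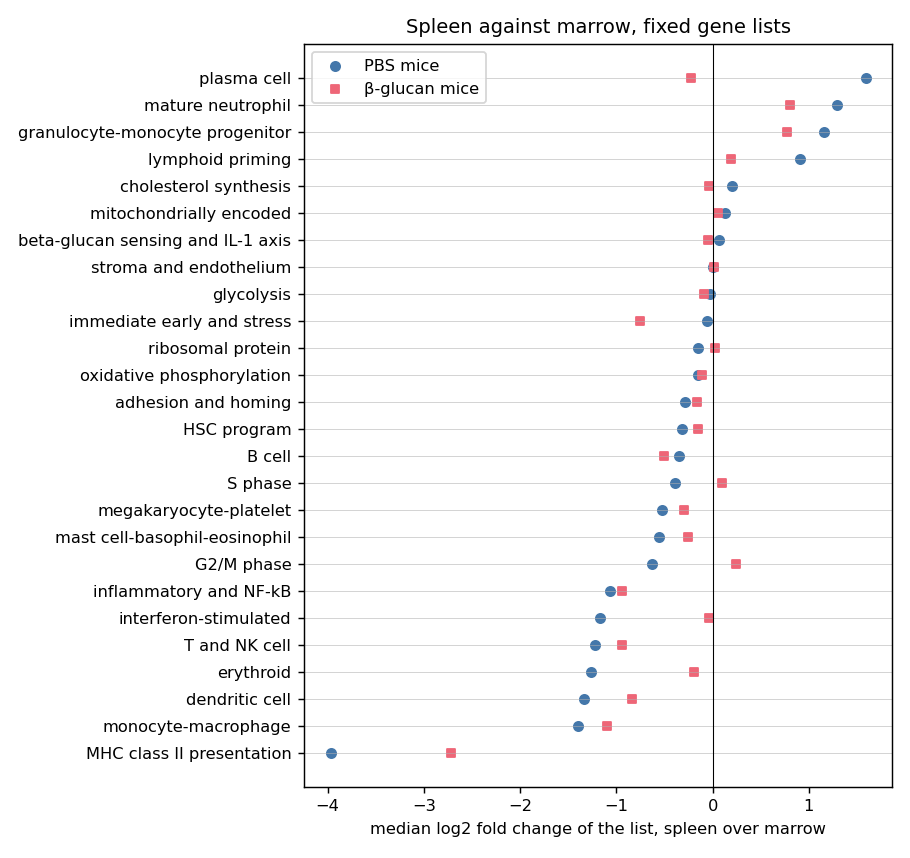
Median log2 fold change, spleen over marrow (x axis), of each of the 26 gene lists (y axis) in PBS mice (circles) and β-glucan mice (squares). MHC class II lies at -3.97 and -2.72.

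The fifth comparison set spleen against marrow in β-glucan mice, where 70 genes were higher and 530 lower in spleen. Of these, 50 were higher and 472 lower in both tissue comparisons (6.26 and 53.1 by chance), 7 were opposite, and the fold changes had r = 0.64 across genes, with no shared libraries. Xcr1 (-3.99), Ciita (-3.71), H2-Aa (-3.77), Dnase1l3 (-5.07) and Cd8a (-4.58) were lower. F13a1, a coagulation factor chain of monocytes, had 131 ± 56.0 against 16.0 ± 12.1 (3.09, SE 0.55, limma adjusted p = 0.00659), and Cxcl12 8.53 ± 4.83 against 0.243 ± 0.103 (2.83). Slamf1 (-1.31, adjusted p = 0.0151) was lower, while Mpo (1.75, adjusted p = 0.332) and Cebpa (1.26, 0.0964) were not called. With the plasma score Cebpa was called (1.16, SE 0.21, limma adjusted p = 0.00362) and Mpo was not (1.56, SE 0.45, 0.0792). Procr (-0.85, adjusted p = 0.0499) lost its call in most settings, among them median-of-ratios scaling (0.0503) and edgeR (0.066). Its call also ended without any 1 of the marrow libraries, spleen PBS 1, or spleen β-glucan 2 or 3 (adjusted p = 0.0503 to 0.205). Immunoglobulin shares were 32.5% and 35.5%.

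Camera called 11 lists, and 5 held with an estimated correlation. These were class II (11 of 13 lower; adjusted p = 0.0122 with an estimated correlation), inflammatory (13 of 23 lower; 0.0122), monocyte-macrophage (13 lower and 1 higher of 20; 0.0122), dendritic cell (8 of 17 lower; 0.00922) and mast cell lists (6 lower and 1 higher of 16; 0.0422). Cd83 (-3.07), Vcam1 (-2.16), Ccr7 (-2.78) and Mcpt4 (-3.37) were examples. Granulocyte-monocyte progenitor (1 higher of 23), mature neutrophil (2 of 15) and G2/M (0 of 24) lists were shifted higher, with adjusted p = 0.646, 0.190 and 0.860 with an estimated correlation. B cell (3 of 20 lower), T and NK cell (5 of 22) and immediate early (5 of 24) lists were shifted lower, with adjusted p = 0.646, 0.237 and 0.183 with an estimated correlation. Adjusted over the list alone, 12 class II, 20 inflammatory, 14 macrophage, 10 dendritic, 7 mast, 5 B, 9 T and NK and 11 immediate early genes were lower, and 6 neutrophil genes and 1 progenitor gene higher. Higher and lower genes numbered 35 and 331 with a minimum of 5, 2576 and 2674 with array weights and 468 and 869 without the farthest libraries; higher genes numbered 108 with quantile scaling, 198 with DESeq2 and 260 with the plasma score. Higher genes numbered 118 without marrow PBS 1, 29 and 27 without marrow β-glucan 1 and 2, and 40 and 22 without spleen β-glucan 2 and 3, and lower genes 342 without spleen β-glucan 3.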

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

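The plasma score tests, the slope from the other tissue and the farthest libraries left out were chosen only after the result was seen. The β-glucan effect differed between spleen and marrow for 54 genes by the test of the difference itself, which flagged the results here. Positive differences on the log2 scale (spleen effect minus marrow effect) were 2.87 for Mcpt1, 2.30 for Iigp1, 2.21 for Ccn3, 2.05 for H2-DMb1, 1.55 for Cd36, 1.37 for Ifit1, 1.30 for Cmpk2, 1.19 for Ifih1 and 1.13 for Gbp2. Negative ones were -6.40 for Ighv12-3, -4.95 for Ighv1-63, -4.51 for Igkv14-100, -4.22 for Slpi, -4.13 for Igkv1-99, -2.07 for Creld2 and -1.67 for Gadd45b. The camera test of the difference called 9 lists, with medians of 1.32 for erythroid, 1.13 for interferon-stimulated, 1.00 for MHC class II, 0.86 for G2/M, 0.52 for S phase, -0.18 for cholesterol synthesis, -0.51 for mature neutrophil, -0.72 for immediate early and -1.83 for plasma cell genes. None of these lists held with an estimated correlation.

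The effects ran in opposite directions (r = -0.51 across genes), which 1 library does not account for, since the correlation farthest from that value on leaving out each library was -0.40. Of 100 drawn splits within each tissue, counting the real grouping, 2 gave a correlation as far below 0 (lowest other -0.57, highest 0.57). A count of genes as large came from 1 of them (highest other 7). The splits regrouped marrow and spleen libraries separately, which is valid only if these came from different mice. No label says so, and the splits therefore cannot decide whether chance gave the correlation or the 54 genes. That count of genes ran from 1 without marrow PBS 2, marrow β-glucan 1 or spleen PBS 2 to 213 without spleen β-glucan 1. For lists, 78 of 100 splits gave 9 or more (highest other 17), so chance is not excluded. A plasma cell share that differed between single libraries stays open, since the correlation with the plasma score was -0.65 where the construction of that test alone gives -0.37. With the slope taken from the other tissue, the covariance left was 0.601 of the original, from -0.0459 without marrow β-glucan 3 to 1.605 without marrow PBS 1, so the share of the pattern that plasma cells may explain cannot be told apart from a tissue-specific β-glucan effect. That biological effect was not tested separately.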

How the results depend on the processing

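The plasma score, the farthest libraries left out and the removal of immunoglobulin genes were chosen only after the data were seen. Slpi and Mcpt1 in marrow kept their calls in every setting run except the fit of the groups compared, where both missed the threshold. All 4 spleen calls lost theirs in at least 1 setting, and of 16 named genes for the difference between tissues, 1 kept its call in all planned settings. Of called genes named in the tissue contrasts, 85 of 105 in PBS mice and 45 of 67 in β-glucan mice did so. The median shift over all genes was under 0.1 with each scaling. Array weights ran from 0.0471 to 69.8 and their fit stopped before converging, so the counts with them deserve no trust. With 3 libraries per group, leaving out 1 leaves 2, and depth limits genes near 1 scaled CPM. No paired analysis was possible because replicate numbers follow the order of deposit. Except where fewer samples or genes were used, the cause was not tested.

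The marrow count of 2 was 9 with a pseudocount of 4, 20 with array weights, 0 with only the groups compared, 116 with DESeq2, 4 with the plasma score, 17 without the farthest libraries and 2 to 4 with 1 library left out. For spleen, 4 became 2 without a filter, 0 with quantile scaling, only the groups compared, edgeR or immunoglobulin genes removed (which took 2 of the 4 out of the test), 3621 with array weights, 114 with DESeq2, 3 with the plasma score (other genes, all higher, while the 4 kept their sign and lost their calls), 39 without the farthest libraries and 0 to 5 with 1 library left out. The 54 genes for the difference became 1602 with array weights, 537 with DESeq2, 34 with the plasma score, 459 without the farthest libraries and 1 to 213 with 1 library left out. The averaged effect gave 3 genes with array weights, 1 with DESeq2 and 0 to 1 with 1 library left out, against 0 by limma and edgeR (382 at an unadjusted p under 0.05).

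For tissue in PBS mice, higher genes were 761 with only the groups compared, 537 with the plasma score and 664 to 1383 with 1 library left out, and lower genes 1041 to 1432. In β-glucan mice, higher and lower genes were 35 and 331 with a minimum of 5, 2576 and 2674 with array weights, 468 and 869 without the farthest libraries, and 22 to 118 and 342 to 618 with 1 library left out. Higher genes were 108 with quantile scaling, 198 with DESeq2 and 260 with the plasma score. The higher share of calls there was 11.7%, against 49.1% with array weights, 22.1% with DESeq2, 26.1% with the plasma score and 35% without the farthest libraries.

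Lists called with an estimated correlation were 0 for marrow, spleen, their difference, the average and tissue in PBS mice, and 5 for tissue in β-glucan mice. Fry called 1 in marrow, 1 in spleen, 1 for the difference and 0 for the average by direction, and 3, 1, 4 and 0 in either direction. For tissue, fry called 11 by direction and 22 in either direction in PBS mice, and 9 and 16 in β-glucan mice. With 1 library left out, list counts were 5 to 11 in marrow, 8 to 17 in spleen, 8 to 13 for the difference, 8 to 13 for the average, 13 to 16 in PBS mice and 9 to 14 in β-glucan mice. The genes called in both tissues for β-glucan numbered 1 when adjusted and 68 at an unadjusted p under 0.01, all with opposite signs, and the correlation of effects was -0.52 to -0.40 with 1 library left out.

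Directions turned as follows, with the adjusted p in the new direction. With the plasma score, the loss of the plasma cell list's shift is largely built in, since 11 of its 19 genes make up the score. Its turn of direction therefore tests nothing. With the plasma score in marrow these were plasma cell 0.494, oxidative phosphorylation 0.0241, G2/M 0.000216 and ribosomal protein 0.0914. In spleen they were plasma cell 0.432, erythroid 0.822, S phase 0.011 and G2/M 0.432, and for the difference 0.474, 0.0705, 3.29e-07 and 0.018. For tissue in PBS mice they were 0.223, 0.567, 1.19e-08 and 9.35e-05, and Cenpe turned to 0.05 on the log2 scale. Without marrow PBS 1, oxidative phosphorylation (0.0894) and ribosomal protein (0.624) turned in marrow. In the average, G2/M turned without marrow PBS 3 (0.977), immediate early without spleen PBS 2 (0.863) and T and NK cell without spleen β-glucan 2 (0.634). Without the farthest libraries, oxidative phosphorylation in marrow (0.972), HSC in the average (0.506) and S phase in PBS mice (0.774) turned. With 1 library left out, adjusted p in marrow ran from 1.80e-05 to 0.768 for oxidative phosphorylation and 9.56e-09 to 0.624 for ribosomal protein. In the average it ran from 1.87e-08 to 0.634 for T and NK cell, 1.25e-06 to 0.977 for G2/M and 0.00138 to 0.863 for immediate early genes.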

Other observations

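The tests of plasma cells, mature B cells, conventional dendritic cells, exchanged tissue labels and the class II and progenitor parts were chosen only after the result was seen. The heavy-chain constant genes counted were Ighm, Ighd, Ighg1, Ighg2b, Ighg2c, Ighg3, Igha and Ighe, without Ighg2a. Among their reads, Ighm made up 97.8% ± 0.230 in marrow PBS and 98.4% ± 0.436 in marrow β-glucan. In spleen it made up 99.3% ± 0.0906 with PBS and 98.6% ± 0.416 with β-glucan (SD, n = 3). Ighg3 made up 0.908% ± 0.116 and 0.536% ± 0.0367 in marrow, and 0.159% ± 0.0126 and 0.361% ± 0.0372 in spleen, with PBS and β-glucan. Ighg2c made up 0.528% ± 0.0371 and 0.260% ± 0.0624 in marrow, and 0.0481% ± 0.0138 and 0.354% ± 0.0766 in spleen. V segment use was spread over an effective number of 9.47 to 28 segments per library and family, and segments share reads with close copies.

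Among the 54 genes whose β-glucan effect differed between tissues, several outside the naming rule were picked after their values were seen. Manf (-1.36), Hyou1 (-1.27), Sdf2l1 (-1.43) and Selenom (-2.19), which encode proteins of the endoplasmic reticulum, differed downward, as did the plasma cell list (median -1.83). Parp12 (1.38), Irgm1 (0.96), Slfn5 (1.22) and Tgtp1 (1.53) differed upward. Genes picked in this way test no gene group. Some lists not called had a median above 0 but were tested lower. These included β-glucan sensing in marrow (0.04) and between tissues in PBS mice (0.06), mast cell genes in spleen (0.01), B cell (0.03) and interferon-stimulated genes (0.03) in the average, stroma in PBS mice (0.01) and glycolysis for the difference (0.000425).

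Immunoglobulin RNA was high in each library (13.1% to 56.0% of reads). The B cell list did not follow the immunoglobulin share over the 12 libraries (r = 0.0518), though r was 0.65 in marrow and 0.07 in spleen. A correlation cannot show whether mature B cells were present. Ighd, the heavy chain of IgD, made up only 0.000552% to 0.0146% of heavy-chain constant reads per library. That argues against B cells expressing IgD as the main source of this RNA, while other mature B cells stay open as a source. Plasma cells among the sorted cells are a candidate source, since their other genes had r = 0.990 with that share, at levels such as 652 ± 103 for Creld2 in spleen PBS. A lineage-negative, Kit-positive gate would be meant to remove such cells. No biological explanation was tested.

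With the plasma score the class II list in PBS mice went from a median of -3.97 to -3.56 (the same 12 members lower). The progenitor list went from 1.16 to 2.42 (11 higher and 2 lower before, 13 higher after, 7 of them called before). Plasma scores did not overlap between tissues in PBS mice (highest 7.03 in marrow, lowest 7.645 in spleen). Both adjustments thus reach beyond shared scores and cannot decide by themselves whether plasma share gave these medians. The class II median kept its direction and most of its size, while the progenitor list changed in median and members. For all calls in PBS mice plasma share stays open, since 28.7% were kept (147 of 1260 higher, 11.7%, and 619 of 1413 lower, 43.8%). The median of higher genes went from 0.946 to 0.333 (SE 0.223 to 0.277) and that of lower ones from -1.08 to -0.96 (SE 0.205 to 0.316). In β-glucan mice the plasma score kept 597 of 600 tissue calls, at immunoglobulin shares of 32.5% in spleen and 35.5% in marrow. These values argue against plasma share as the source of those calls. Among them, 50 higher and 472 lower genes were also called in PBS mice. Conventional dendritic cells among the marrow cells may contribute, since 12 of 12 markers were lower in spleen in PBS mice (median -4.09) and 10 of 12 in β-glucan mice (-2.80; 6 of the 12 also in a fixed list), with H2-Aa at 1674 in marrow, although the gate would be meant to remove them. Exchanged tissue labels are a further candidate. In PBS mice 8 tested spleen markers had a median of -1.04 (5 lower, 0 higher) and 11 marrow markers 1.92 (6 higher, 1 lower). In β-glucan mice these were -0.96 (4 lower, 0 higher) and 0.96 (1 higher, 1 lower). Of these markers 5 and 9 are in a fixed list, and every called marker is among them. The others were not called in PBS mice: Nkx2-3 (-0.51), S1pr3 (0.86) and Cd1d1 (0.03) for spleen, Fcnb (0.80) and Spp1 (-0.73) for marrow. The called markers thus repeat cell type lists, so cell content and exchanged labels cannot be told apart. A biological difference of the tissues stays open and was not tested, and no library was regrouped.

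Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For genes, 1 of 10 splits reached the real count in each contrast: 2 in marrow (highest other 1), 4 in spleen (2), 2673 for tissue in PBS mice (0) and 600 in β-glucan mice (1). For lists, 9 of 10 splits reached the real 8 in marrow (highest other 14), 5 the 13 in spleen (14), 3 the 15 in PBS mice (15) and 7 the 11 in β-glucan mice (17). For the average, 52 of 100 drawn splits reached the real 11 lists (highest other 16), so chance is not excluded there. Its real count of 0 genes is reached by 100 of 100 splits by construction (highest other 7), which tests nothing.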
